A study of Mus musculus with 22 samples.

How the data were processed

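Lymphocytes were isolated from pooled mammary tumours of 20- to 24-week-old female PyMT C57BL/6 mice by collagenase and DNase digestion and Percoll separation and sorted by flow cytometry, and cDNA was amplified with the SMARTer method, per the labels' protocols. Reads were processed with BWA 0.7.5a, Picard and HTSeq, and the genome builds named are mm9 and NCBIM37, per the submitters' processing notes; the role of each build and the counting settings are not given in the sources used here. The deposited table holds whole counts per gene for 22 libraries, made by the authors with HTSeq per the submitters' processing notes. The libraries cover 11 populations with 2 libraries each, taken from the sample titles. Titles spelled ILC1I and ILC1l were treated as 1 population. Nothing in the labels says that replicate libraries come from separate animals, and tumours were pooled. The p-values of single genes therefore measure only the spread between these libraries, estimated over all populations of a fit.

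Of 37620 table entries, 32897 (99.02% of counts) were matched to current gene symbols with a GRCm38 annotation, used for names alone, and 3 symbols were shared by several entries; no coordinates are given because the builds differ. Members of near-identical families (Klra, Klrb, Klrc and the granzyme genes Gzmc to Gzmg) may have shared or lost reads, so their single values are uncertain. Whether strand was used in counting is not given in the sources used here.

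Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), with limma 3.58.1 for camera and DESeq2 1.42.0 as an alternative. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9. The first set of 5 populations (10 libraries) and the second of 6 (12 libraries) were fitted separately with 1 mean per population, testing 15727 and 16828 genes. CPM are TMM-scaled. For each of the 8 comparisons of population pairs with calls, both libraries of 1 population lay above both of the other in every called gene (332 of 332 in the first comparison, where 44.9% of all tested genes did so and chance gives 33.3%).

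Beside the pairwise comparisons, the mean of 3 differences in the second set and the differences between them (interaction contrasts) were tested. For a gene with 0 counts in a population, the fold is a lower bound computed with 3 counts over that population's libraries, and list medians use such bounds. These bounds and the values of 3 counts per library cover counting error only, since PCR copies were not marked by molecular identifiers.

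Lists of genes were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. The preset value treats genes as nearly independent. For the NK receptor list in NK1.1+ against PD1+ CD8α+ T cells, camera's adjusted p was 5.47e-91 with it and 0.00771 with the estimated one. The 23 lists, written before the data were examined, cover cytotoxicity, inhibitory receptors, NK receptors, tissue residency, egress, mature NK cells, T-cell receptor signalling, type 3 genes, type 1 genes, T helper genes, cytokine receptors, lineage transcription factors, chemokines and their receptors, cell cycle, immediate early genes, interferon response, glycolysis, and markers of myeloid, B, epithelial, stromal, erythroid and mast cells. They were written from general knowledge. The immediate early list was set as a list of immediate early and dissociation stress genes. Old symbols Cd244, Pkm2 and Emr1 were read as Cd244a, Pkm and Adgre1, and Hbb-b1 and Hbb-b2 were not found. 

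Named genes follow a rule: 20 key genes in every comparison, the 6 called genes of largest rise and the 6 of largest fall with at least 20 CPM in the higher population and no overlap of libraries (10 each way for the mean of 3 differences, 3 for interaction contrasts), up to 2 called members each way of every list, and genes shared by 3 comparisons. Predicted genes, olfactory receptors and receptor segments were left out. Not every gene picked is printed. The groups, comparisons, tests, lists, this rule and the alternatives, apart from those named next, were set before the data were examined. Chosen after seeing the data were the fits without genes that follow the epithelial or myeloid lists (correlation above 0.8 of log2 CPM with the mean log2 CPM of the list, over 22 libraries for the epithelial list and without the TCRγδ+NK1.1− libraries for the myeloid list), the mean without TCRγδ+ populations, and the patterns weighed in the closing part.

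The test was tested on simulated data drawn from these libraries' means and sizes, with 50 genes changed at each of 4 sizes. For NK1.1+ against PD1+ CD8α+ T cells (15097 genes) it recovered 0, 38, 84 and 100% of genes changed by a log2 of 1, 2, 4 and 6, with 6 false calls, 5.1% of its calls. For TCRαβ+ ILTC1 against TCRβ+CD8α+NK1.1− cells (15919 genes) it recovered 0, 24, 74 and 80%, with 3 false calls, 3.3%. A first version with sizes of 1 and 2 alone missed the recovery limit set beforehand, and the larger sizes were then added. The absence of a call therefore does not show the absence of a change. Changed genes were drawn only above a floor of mean CPM, and the simulated populations otherwise shared their means. Recovery of weakly expressed genes, and false calls where populations differ in RNA of other cells, were not tested.

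Alternatives were RLE and upper-quartile scaling, other filters, all 22 libraries or only those compared in the fit, DESeq2, stricter thresholds, the replicate number as a block, the estimated correlation, and leaving out each library in turn, where the lone library of a population is assumed to vary like the other populations.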

Results

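RNA was sequenced from 11 lymphocyte populations sorted out of pooled mammary tumours of female PyMT mice aged 20 to 24 weeks, with 2 libraries per population and 22 in all. PyMT mice express a viral oncogene in the mammary gland and develop tumours there. A first set holds 5 populations named by their surface markers: TCRβ+CD8α+NK1.1+, TCRβ+CD8α+PD1+, TCRβ+CD8α+PD1−NK1.1−, TCRβ+CD8α−NK1.1+ and TCR−NK1.1+ cells. A second set holds 6: ILC1l cells (type 1-like innate lymphoid cells), cNK cells (conventional natural killer cells), TCRαβ+ and TCRγδ+ ILTC1 cells (type 1 innate-like T cells), TCRβ+CD8α+NK1.1− cells and TCRγδ+NK1.1− cells. Total counts per library ran from 8696335 (TCRγδ+NK1.1− replicate 1) to 20602715 (TCRαβ+ ILTC1 replicate 1), and 12866 to 21446 genes had at least 1 count. A count of 3 in a library equalled 0.146 to 0.345 CPM, counts scaled to a library total of 1e+06. Below, values are mean CPM ± SD with n = 2 libraries, differences are log2 fold changes ± SE, and adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless camera, a test of whole gene lists, is named. Where a camera call was lost with a correlation estimated from the data, that adjusted p follows; the other camera calls held. Camera calls of the pairwise comparisons and of the mean that are not given below were all lost with it.

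Genes of other cell types were measured before the populations were compared. The summed CPM of 16 mammary epithelial and tumour genes, among them keratin and casein genes, was 7304 and 4118 in the TCR−NK1.1+ libraries and 4683 and 333 in the TCRβ+CD8α−NK1.1+ libraries. In the TCRγδ+NK1.1− libraries it was 4509 and 2477, and in the TCRβ+CD8α+NK1.1− libraries 1740 and 3204. It stayed between 23.39 and 126.3 in the other 14 libraries. The summed CPM of 20 myeloid genes reached 19535 and 48216 in the TCRγδ+NK1.1− libraries, which also held 126.8 and 87.3 CPM of erythroid and platelet genes. Myeloid sums in the cNK libraries were 930.5 and 3538, and in the TCRαβ+ ILTC1 libraries 2384 (replicate 1) and 401.4 (replicate 2). They were 2639 and 2666 in the TCRβ+CD8α+NK1.1− and 2173 and 2026 in the TCR−NK1.1+ libraries.

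**Figure D1:**
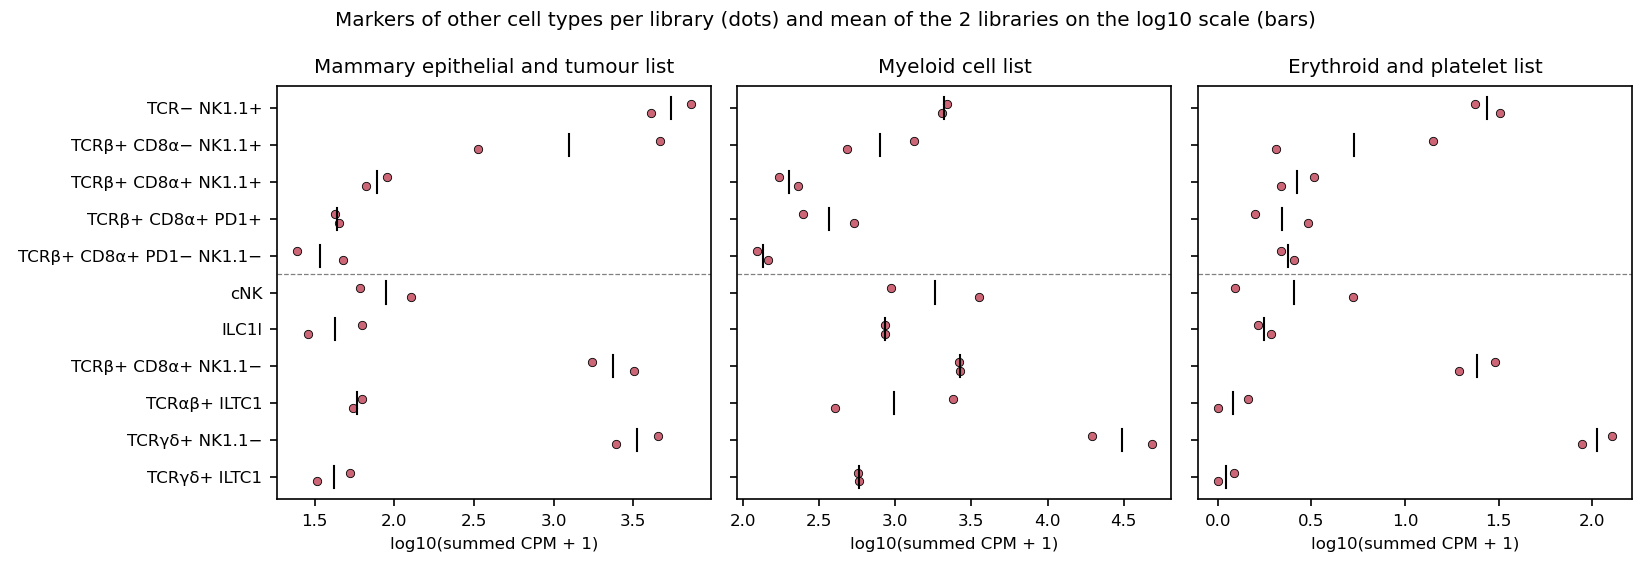
Summed CPM of the mammary epithelial and tumour, myeloid, and erythroid and platelet gene lists on a log10(summed CPM + 1) axis, 1 dot per library and bars at the mean of 2 libraries on that scale, for 11 populations. The epithelial sum ranged from 333 to 7304 in the 8 libraries of the 4 populations that carried it most, and the myeloid sum peaked at 48216 in a TCRγδ+NK1.1− library.

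The first comparison asked how NK1.1-expressing CD8α+ T cells differ from PD1+ CD8α+ T cells, PD1 being an inhibitory receptor of stimulated T cells. Granzyme genes differed in direction: Gzmb was at 14393 ± 2646 CPM in NK1.1+ and 1017 ± 378 CPM in PD1+ cells (3.82 ± 0.44, adjusted p = 0.00209). Gzmk, the gene of another granzyme, was at 22.1 ± 8.22 and 956 ± 78.5 CPM (−5.43 ± 0.51, adjusted p = 0.00078). Gzmc, a granzyme gene, was at 274 ± 59.1 and 2.2 ± 1.67 CPM (6.99 ± 0.70, adjusted p = 0.000944). Fcer1g, which encodes a signalling adaptor of innate receptors, was 95.6-fold higher in NK1.1+ cells at 2065 ± 188 CPM (6.58 ± 0.55, adjusted p = 0.00057). The integrin gene Itgae, whose product CD103 binds E-cadherin on epithelium, was 6.09-fold higher at 1347 ± 98.4 CPM (2.61 ± 0.35, adjusted p = 0.00489).

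For the sort markers themselves, Klrb1c, which encodes NK1.1, was at 1105 ± 0.555 and 1.97 ± 1.65 CPM (9.08 ± 0.63, adjusted p = 0.000166). Pdcd1, which encodes PD1, was at 36.4 ± 19.8 and 1702 ± 262 CPM (−5.55 ± 0.52, adjusted p = 0.000777). Cd8a differed by 0.49 ± 0.39 (adjusted p = 0.788).

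In total 332 of 15727 tested genes differed, 172 higher and 160 lower in NK1.1+ cells. Of the 30 NK receptor genes 21 were higher and 9 not called (26 higher adjusted over the list alone; camera adjusted p = 5.47e-91), with a median of 4.61. Ncr1, the gene of the activating receptor NKp46, was at 39.3 ± 31.3 CPM against 0 counts, at least 352-fold higher (adjusted p = 0.00417). Klra7, a member of the near-identical Ly49 receptor family, was at 993 ± 116 against 6.43 ± 5.32 CPM (7.25 ± 0.66). S1pr3, a sphingosine phosphate receptor gene, was at 59.9 ± 2.36 CPM against 0 counts, at least 535-fold higher (adjusted p = 0.000885). Of the 20 tissue residency genes 5 were higher, 1 lower and 14 not called (9 and 3 adjusted over the list alone; camera adjusted p = 7.91e-05, adjusted p = 0.276 with an estimated correlation). Among them were Itga1, the gene of the collagen receptor CD49a (2.66 ± 0.47, adjusted p = 0.0167), Zfp683, which encodes the residency factor Hobit (2.54 ± 0.44, adjusted p = 0.0145), and Xcl1, a dendritic cell attractant (3.30 ± 0.45, adjusted p = 0.00508).

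Genes lower in NK1.1+ than in PD1+ cells included the costimulator gene Cd28 (−5.31 ± 0.35, adjusted p = 0.000166), the inhibitory receptor gene Ctla4 (−4.15 ± 0.41, adjusted p = 0.000885) and Il7r, the gene of the interleukin 7 receptor (−5.83 ± 0.57, adjusted p = 0.000885). Eomes, a T-box factor of cytotoxic cells, was at 8.31 ± 0.311 and 129 ± 7.32 CPM (−3.95 ± 0.36, adjusted p = 0.00074). The cytokine gene Ifng was at 52.4 ± 15.9 and 332 ± 29.8 CPM (−2.66 ± 0.34, adjusted p = 0.00417). Coch, which encodes an extracellular protein, had 0 counts in NK1.1+ and 96.3 ± 48.2 CPM in PD1+ cells, at least 769-fold lower (adjusted p = 0.00489). Tbx21, the T-bet gene (0.06 ± 0.52, adjusted p = 1), and the perforin gene Prf1 (−1.16 ± 0.33, adjusted p = 0.159) were not called.

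By list, 9 of 20 inhibitory receptor genes were lower, 2 higher and 9 not called (11 and 3 adjusted over the list alone; camera adjusted p = 2.51e-10, adjusted p = 0.0744 with an estimated correlation). Of 20 interferon response genes 9 were lower and 11 not called (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.71e-21), with Iigp1, an interferon-induced GTPase gene, at −4.32 ± 0.60. Of 19 chemokine and chemokine receptor genes 4 were lower, 1 higher and 14 not called (camera adjusted p = 4e-07, adjusted p = 0.0744 with an estimated correlation). T-cell receptor signalling genes were lower as a list, 5 of 20 called (camera adjusted p = 9.25e-06, adjusted p = 0.142 with an estimated correlation). Egress genes were lower too, 5 of 18 called (camera adjusted p = 0.000109, adjusted p = 0.142 with an estimated correlation).

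Camera also placed the T helper list lower, with 2 of 14 genes called (camera adjusted p = 0.00825, adjusted p = 0.227 with an estimated correlation). The type 1 list had 2 of 15 genes higher and 3 lower (camera adjusted p = 0.00675, adjusted p = 0.328 with an estimated correlation). The lineage transcription factor list had 1 of 23 higher and 3 lower (camera adjusted p = 0.0261, adjusted p = 0.297 with an estimated correlation). The B-cell list had 3 of 9 genes higher in NK1.1+ cells, Cd22 and Cd79b among them (camera adjusted p = 0.0119, adjusted p = 0.142 with an estimated correlation). The list summed to 1017 and 884.9 CPM against 223.7 and 137.7 CPM in PD1+ cells, of which the immunoglobulin gene Ighm made up 954 and 825 against 219 and 132 CPM. Igkc, an immunoglobulin gene outside the list, ran the other way, at 0 and 0.167 against 69 and 42.6 CPM. The myeloid list lay lower in NK1.1+ cells, though its only called gene of 20 was higher (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.68e-05, adjusted p = 0.276 with an estimated correlation). The cytotoxicity list (4 of 20 higher, 2 lower; camera adjusted p = 0.0596), the mature NK list (3 of 17 higher, 2 lower; 0.0596), the immediate early list (0.0514), the cytokine receptor list (2 of 17 higher, 3 lower; 0.731) and the cell cycle and glycolysis lists (0.972 each) were not called by camera.

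Leaving out each of the 4 libraries in turn gave 119 calls (without NK1.1+ replicate 1), 116 (NK1.1+ replicate 2), 170 (PD1+ replicate 1) and 137 (PD1+ replicate 2). Klrb1c, Pdcd1, Klra7, Gzmb, Gzmc, Gzmk, Fcer1g, Ncr1, S1pr3, Itgae, Xcl1, Cd28, Ctla4, Il7r, Eomes and Coch kept an adjusted p under 0.05 in all 4 of these fits, whereas Itga1, Zfp683 and Cd22 kept it in none, Iigp1 and Igkc in 2 and Ifng and Cd79b in 3.

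The second comparison asked how the same NK1.1+ cells differ from CD8α+ T cells with neither NK1.1 nor PD1 on their surface. Ccr7, the gene of a lymph node homing receptor, was at 0.418 ± 0.237 against 379 ± 225 CPM (−9.80 ± 0.81, adjusted p = 0.00116). S1pr1, a receptor gene for exit from tissue, was at 5.05 ± 3.12 against 338 ± 84.2 CPM (−6.06 ± 0.55, adjusted p = 0.00139). Il7r was at 2.54 ± 1.83 against 520.3 ± 80.4 CPM (−7.67 ± 0.62, adjusted p = 0.00116). Ly6c2, a surface protein gene of circulating T cells, was at 64 ± 1.82 against 1411 ± 239 CPM (−4.46 ± 0.34, adjusted p = 0.00102). Gzmb was 6.96-fold higher in NK1.1+ cells (2.80 ± 0.42, adjusted p = 0.0109).

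In total 280 genes differed, 144 higher and 136 lower in NK1.1+ cells. Klrb1c (5.99 ± 0.54, adjusted p = 0.00139), Ncr1 (7.15 ± 0.96, adjusted p = 0.00968), S1pr3 (6.42 ± 0.71, adjusted p = 0.00373), Gzmc (4.80 ± 0.62, adjusted p = 0.00559) and Fcer1g (3.92 ± 0.49, adjusted p = 0.00434) were higher. So were Tnfrsf9, which encodes the costimulator 4-1BB (3.05 ± 0.36, adjusted p = 0.00373), Ikzf2, a zinc-finger factor gene (2.92 ± 0.44, adjusted p = 0.0118), and Il2rb, an interleukin 2 and 15 receptor gene (1.87 ± 0.32, adjusted p = 0.0212). Itgae (1.59 ± 0.34, adjusted p = 0.0505), Itga1 (1.86 ± 0.46, adjusted p = 0.0921) and Pdcd1 (−1.44 ± 0.44, adjusted p = 0.197) were not called. Lower genes included Lef1, a factor gene of naive T cells (−4.60 ± 0.53, adjusted p = 0.00361), Btla, an inhibitory receptor gene (−5.88 ± 0.69, adjusted p = 0.00373), and Cd28 (−4.66 ± 0.34, adjusted p = 0.00102). Ccr9, the gene of a gut homing receptor, had 0 counts against 59.1 ± 63.4 CPM, at least 472-fold lower (adjusted p = 0.0243).

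Of 18 egress genes 10 were lower and 8 not called (15 lower adjusted over the list alone; camera adjusted p = 1.42e-43), with a median of −3.27. Of 30 NK receptor genes 15 were higher and 15 not called (22 higher adjusted over the list alone; camera adjusted p = 6.65e-55). Interferon response genes were lower, 6 of 20 called (14 lower adjusted over the list alone; camera adjusted p = 5.14e-16). The cytotoxicity list had 6 of 20 genes higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 2e-04, adjusted p = 0.32 with an estimated correlation). The residency list had 2 of 20 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 3.37e-07, adjusted p = 0.215 with an estimated correlation). Of the inhibitory receptor list 4 of 20 genes were higher and 3 lower (camera adjusted p = 0.0234, adjusted p = 0.388 with an estimated correlation). For 17 cytokine receptor genes the median was 0.02 although camera placed the list lower (adjusted p = 0.0316, adjusted p = 0.32 with an estimated correlation).

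Without 1 library the calls numbered 46 (NK1.1+ replicate 1), 59 (NK1.1+ replicate 2), 61 (PD1−NK1.1− replicate 1) and 105 (PD1−NK1.1− replicate 2). Ccr7, S1pr1, Il7r, Ly6c2, Klrb1c, Ncr1, S1pr3, Gzmc, Tnfrsf9, Lef1, Btla and Cd28 kept their calls in all 4 fits, and Gzmb did in 2, Fcer1g in 3, Ccr9 in 1 and Ikzf2 and Il2rb in none.

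The third comparison, PD1+ against PD1−NK1.1− CD8α+ T cells, asked what goes with PD1 among conventional CD8α+ T cells. Tox, which encodes a factor of chronically stimulated T cells, was at 1015 ± 89.9 and 175 ± 34.6 CPM (2.53 ± 0.26, adjusted p = 0.00622). The inhibitory receptor gene Lag3 was at 159 ± 42 and 11.7 ± 8.42 CPM (3.76 ± 0.61, adjusted p = 0.0318). Pdcd1 was 17.3-fold higher (4.11 ± 0.48, adjusted p = 0.0112). Satb1, a chromatin organiser gene, was at 4.73 ± 0.387 and 193 ± 70.2 CPM (−5.35 ± 0.54, adjusted p = 0.00622).

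Of 71 genes that differed, 29 were higher and 42 lower in PD1+ cells. Coch was higher (7.79 ± 1.12, adjusted p = 0.0242), as was Adora3, an adenosine receptor gene (3.94 ± 0.69, adjusted p = 0.0475). The naive and memory factor genes Tcf7 (−2.30 ± 0.34, adjusted p = 0.0212) and Lef1 (−4.09 ± 0.52, adjusted p = 0.0128) were lower. So were S1pr1 (−3.16 ± 0.48, adjusted p = 0.0229), Ccr7 (−4.19 ± 0.60, adjusted p = 0.0205) and Il12rb2, an interleukin 12 receptor gene (−3.66 ± 0.55, adjusted p = 0.0223). Gzmb (−1.02 ± 0.39, adjusted p = 0.584), Ifng (1.38 ± 0.33, adjusted p = 0.156) and Eomes (1.45 ± 0.32, adjusted p = 0.113) were not called. Inhibitory receptor genes were higher, 6 of 20 called (12 adjusted over the list alone; camera adjusted p = 1.05e-30). Egress genes were lower, 7 of 18 called (12 adjusted over the list alone; camera adjusted p = 9.3e-37). NK receptor genes were lower as well, 6 of 30 called (14 adjusted over the list alone; camera adjusted p = 8.46e-26, adjusted p = 0.0552 with an estimated correlation). The myeloid list, of which no gene was called, lay higher in PD1+ cells (camera adjusted p = 0.000164, adjusted p = 0.446 with an estimated correlation).

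Without PD1+ replicate 1 or 2 the calls numbered 29 and 14, and without PD1−NK1.1− replicate 1 or 2 they numbered 26 and 30. Tox and Satb1 kept their calls in all 4 fits, Pdcd1, Coch and Lef1 in 2, Lag3, Tcf7, Ccr7 and Il12rb2 in 1, and S1pr1 and Adora3 in none. Without the 770 genes that followed the epithelial genes across the 22 libraries, a choice made after seeing the data, 114 genes were called, 70 of them among the 71.

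A comparison of the NK1.1+ CD8α+ T cells with TCR−NK1.1+ cells asked what separates NK1.1+ cells with and without a T-cell receptor. Gzmc was at 274 ± 59.1 CPM in the T cells and 3115 ± 1500.4 CPM in TCR− cells (−3.51 ± 0.58, adjusted p = 0.021), and Prf1 at 93.5 ± 11.5 and 375 ± 84.3 CPM (−2.00 ± 0.34, adjusted p = 0.024). Eomes (−2.20 ± 0.33, adjusted p = 0.0187) and Ccr2, a chemokine receptor gene (−5.28 ± 0.60, adjusted p = 0.00528), were lower in the T cells. The T-cell receptor genes Cd3e (2.46 ± 0.35, adjusted p = 0.0148) and Trac (2.78 ± 0.33, adjusted p = 0.00691) and the sort marker gene Cd8a (3.31 ± 0.42, adjusted p = 0.00924) were higher. TCR− cells nevertheless held 313 ± 148 CPM of Cd3e. Klrb1c (−0.23 ± 0.43, adjusted p = 0.885), Gzmb (0.85 ± 0.39, adjusted p = 0.334) and Itgae (1.14 ± 0.34, adjusted p = 0.147) were not called.

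Of 242 genes that differed, 42 were higher and 200 lower in the T cells. T-cell receptor signalling genes were higher, 8 of 20 called and 1 lower (17 and 2 adjusted over the list alone; camera adjusted p = 2.34e-21). Mature NK genes were lower, 6 of 17 called (9 adjusted over the list alone; camera adjusted p = 2.46e-09). Part of the 200 belonged to lists of other cell types. Of the epithelial list 5 of 15 genes were lower (14 adjusted over the list alone; camera adjusted p = 3.19e-22, adjusted p = 0.0716 with an estimated correlation), with the keratin gene Krt19 at 1.42 ± 0.233 and 927 ± 572 CPM. Also lower were the myeloid list (6 of 20; camera adjusted p = 4.06e-20, adjusted p = 0.0716 with an estimated correlation) and the stromal list (1 of 9; camera adjusted p = 0.000208, adjusted p = 0.174 with an estimated correlation). Of 3 mast cell genes 1, Cma1, was lower (camera adjusted p = 0.00187, adjusted p = 0.16 with an estimated correlation). Cma1 also stands in the mature NK list and was at 454 ± 85.4 CPM in cNK cells of the second set, so it need not mark mast cells here.

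Without T-cell replicate 1 or 2 the calls numbered 3 and 13, and without TCR− replicate 1 or 2 they numbered 45 and 137. No gene picked by the naming rule kept its call in all 4 fits: Trac did in 3, Cd3e, Cd8a, Ccr2 and Krt19 in 2, Gzmc, Prf1 and Eomes in 1, and Cma1 in none. Without genes that followed the epithelial list, a choice made after seeing the data, 116 were called, 35 higher and 81 lower, 115 of them among the 242.

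Against TCRβ+CD8α−NK1.1+ cells, which asks what CD8α marks among NK1.1+ T cells, the NK1.1+ CD8α+ cells differed in 53 genes, 1 higher and 52 lower. The higher gene was the sort marker gene Cd8a at 2642 ± 5.76 and 66.3 ± 32.1 CPM (5.32 ± 0.47, adjusted p = 0.00264). Il7r (−4.70 ± 0.55, adjusted p = 0.00985), S1pr1 (−3.34 ± 0.49, adjusted p = 0.026), Ly6c2 (−3.00 ± 0.32, adjusted p = 0.00732) and Il18r1, an interleukin 18 receptor gene (−3.63 ± 0.43, adjusted p = 0.00985), were lower. Gzmb (1.07 ± 0.39, adjusted p = 0.402), Itgae (0.86 ± 0.33, adjusted p = 0.448) and Klrb1c (0.25 ± 0.43, adjusted p = 0.983) were not called. Egress genes were lower, 3 of 18 called (8 adjusted over the list alone; camera adjusted p = 3.6e-16, adjusted p = 0.0521 with an estimated correlation). The epithelial list was lower too, 4 of 15 called (12 adjusted over the list alone; camera adjusted p = 5.21e-19, adjusted p = 0.106 with an estimated correlation). So was the myeloid list, with none of 20 called (11 adjusted over the list alone; camera adjusted p = 2.52e-14, adjusted p = 0.119 with an estimated correlation). Without TCRβ+CD8α−NK1.1+ replicate 1 or 2 the calls numbered 138 and 667, and without NK1.1+ CD8α+ replicate 1 or 2 they numbered 5 and 2. Cd8a kept its call in all 4 fits, Il7r in 3 and S1pr1, Ly6c2 and Il18r1 in 2. With genes that followed the epithelial list left out after seeing the data, 22 were called, 21 of them among the 53.

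In the second set, ILC1l were compared with cNK cells to ask what separates these cells of the innate lineage. Gzmc was at 3491 ± 61.2 CPM in ILC1l and 9.37 ± 0.177 CPM in cNK cells (8.54 ± 0.66, adjusted p = 0.000543), while Prf1 was at 555 ± 51.9 and 3299 ± 585 CPM (−2.57 ± 0.42, adjusted p = 0.0191). The residency genes Itgae, at 1519 ± 285 and 5.75 ± 4.94 CPM (8.05 ± 0.82, adjusted p = 0.00193), and Itga1, at 308 ± 63.4 and 5.85 ± 2.78 CPM (5.72 ± 0.42, adjusted p = 0.000543), were higher in ILC1l. Tnfsf10, which encodes the death ligand TRAIL, was 8.55-fold higher (3.10 ± 0.30, adjusted p = 0.00149). The chemokine receptor gene Cxcr6 was at 1186 ± 309.6 and 19.6 ± 10.2 CPM (5.92 ± 0.42, adjusted p = 0.000543).

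In total 171 of 16828 tested genes differed, 102 higher and 69 lower in ILC1l. S1pr1 (−4.35 ± 0.58, adjusted p = 0.00729), the integrin gene Itgam (−3.89 ± 0.66, adjusted p = 0.0244) and the interleukin 18 receptor gene Il18rap (−3.52 ± 0.32, adjusted p = 0.00113) were lower. The same held for Ifng (−2.36 ± 0.37, adjusted p = 0.0156) and Nr4a1, an immediate early gene (−2.93 ± 0.29, adjusted p = 0.00157). Klrb1c (−0.62 ± 0.81, adjusted p = 0.862), Tbx21 (−0.94 ± 0.36, adjusted p = 0.373), Gzmb (1.57 ± 0.40, adjusted p = 0.131) and Eomes (−2.55 ± 1.70, adjusted p = 0.643) were not called. Neither was Itga2, the gene of the NK marker CD49b (−3.88 ± 1.01, adjusted p = 0.141). Eomes was nevertheless at 28.5 ± 1.76 CPM in ILC1l and 167 ± 30 CPM in cNK cells, and Itga2 at 16.5 ± 1.27 and 243 ± 22.5 CPM. A gene's spread is estimated over all 6 populations of the set. Eomes was at 13.9 and 0 CPM in the TCRγδ+ and at 10.2 and 0 CPM in the TCRαβ+ ILTC1 libraries. Cma1, a mast cell protease gene that also stands in the mature NK list, was at 1.22 ± 0.505 and 454 ± 85.4 CPM (−8.53 ± 1.25, adjusted p = 0.0157). Cd3e, a T-cell receptor complex gene, was higher in ILC1l, at 88.4 and 477 CPM in its libraries against 3.38 ± 3.9 CPM (6.40 ± 1.05, adjusted p = 0.0214).

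Of 20 residency genes 9 were higher and 11 not called (13 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.05e-35), with a median of 2.17. Of 18 egress genes 5 were lower and 13 not called (12 lower adjusted over the list alone; camera adjusted p = 4.16e-21). Of 17 mature NK genes 4 were lower and 13 not called (10 adjusted over the list alone; camera adjusted p = 1.95e-16). The immediate early list was lower, 4 of 19 called (10 adjusted over the list alone; camera adjusted p = 1.25e-14). The type 1 list was lower too, 2 of 15 lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 3.98e-06, adjusted p = 0.0653 with an estimated correlation). The inhibitory receptor list was higher, 5 of 20 called and 1 lower (camera adjusted p = 0.00152). The T-cell receptor signalling list was likewise higher, 5 of 20 called and 1 lower (camera adjusted p = 7.2e-06, adjusted p = 0.108 with an estimated correlation). The NK receptor list was not called (3 of 30 higher; camera adjusted p = 0.682). Genes of other cells moved as well: the myeloid list lay lower in ILC1l with none of 20 genes called and a median of −2.73 (camera adjusted p = 2.53e-05, adjusted p = 0.349 with an estimated correlation). Igkc, named after its values were seen, was at 12.8 and 14.4 CPM in the ILC1l libraries and at 1785 and 917 CPM in the cNK libraries, and was not called (−6.63 ± 1.76, adjusted p = 0.152).

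Without ILC1l replicate 1 or 2 the calls numbered 79 and 51, and without cNK replicate 1 or 2 they numbered 34 and 53. Gzmc, Itgae, Itga1, Cxcr6, Tnfsf10, Il18rap and Nr4a1 kept their calls in all 4 fits, S1pr1 and Cd3e in 2, Ifng in 1, and Prf1, Itgam and Cma1 in none.

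TCRαβ+ ILTC1 cells were compared with TCRβ+CD8α+NK1.1− cells to ask what sets the innate-like αβ T cells apart. Gzmb was at 12483 ± 1815 and 1389 ± 803 CPM (3.17 ± 0.42, adjusted p = 0.0228), and Gzmc at 363 ± 151 and 14.6 ± 10.5 CPM (4.64 ± 0.55, adjusted p = 0.0155). Fcer1g was 12.4-fold higher (3.64 ± 0.45, adjusted p = 0.0155), and Ncr1 was at 137 ± 51.9 CPM against 0 counts, at least 1241-fold higher (adjusted p = 0.0387). Itga1 (2.13 ± 0.35, adjusted p = 0.0422) and Il2rb (2.37 ± 0.34, adjusted p = 0.0266) were higher. Gzmk (−4.69 ± 0.57, adjusted p = 0.0155), Pdcd1 (−3.05 ± 0.52, adjusted p = 0.0427), Cd28 (−3.94 ± 0.68, adjusted p = 0.0427) and Themis, a T-cell signalling gene (−3.59 ± 0.63, adjusted p = 0.0456), were lower.

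Of 88 genes that differed, 41 were higher and 47 lower in TCRαβ+ ILTC1 cells. Klrb1c was at 1085 ± 121 and 46.8 ± 57.7 CPM (4.54 ± 0.94) and was not called (adjusted p = 0.0718), nor were Itgae (2.49 ± 0.63, adjusted p = 0.123) and Il7r (−3.18 ± 0.64, adjusted p = 0.0659). Of 30 NK receptor genes 12 were higher and 18 not called (21 higher adjusted over the list alone; camera adjusted p = 1.18e-48). The cytotoxicity list was higher, 3 of 20 called and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 1.95e-05, adjusted p = 0.0572 with an estimated correlation). The residency list was higher, 2 of 20 called (5 and 1 lower adjusted over the list alone; camera adjusted p = 1.97e-05, adjusted p = 0.074 with an estimated correlation). The immediate early list was lower, 4 of 19 called, Nr4a1 and Fos among them (camera adjusted p = 1.4e-07, adjusted p = 0.0889 with an estimated correlation). Fos was at 70.7 ± 3.08 and 419 ± 231 CPM. In the first set it was at 429.6 ± 47.3 CPM in TCR−NK1.1+ cells, whose libraries also held epithelial genes. It was at 75.1 ± 6.8 CPM in PD1+ and 96.4 ± 26.4 CPM in PD1−NK1.1− cells. Whether dissociation stress or RNA of other cells set this list's level was not tested. Epithelial genes were lower, 2 of 15 called (12 adjusted over the list alone; camera adjusted p = 2.13e-13, adjusted p = 0.0686 with an estimated correlation), with Krt8, a keratin gene, at 2.32 ± 1.98 and 257 ± 134 CPM. Other lists of other cells lay lower as well: myeloid (camera adjusted p = 0.00222, adjusted p = 0.48 with an estimated correlation), stromal (0.000729 and 0.0686) and erythroid (0.00112 and 0.176).

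Without TCRαβ+ ILTC1 replicate 1 or 2 the calls numbered 840 and 11, and without TCRβ+CD8α+NK1.1− replicate 1 or 2 they numbered 36 and 11. Gzmc and Fcer1g kept their calls in all 4 fits, Gzmb and Gzmk in 3, Fos in 2, and Ncr1, Itga1, Il2rb, Nr4a1, Pdcd1, Cd28, Themis and Krt8 in 1. Without genes that followed the epithelial list, chosen after seeing the data, 39 were called, 20 higher and 19 lower, all 39 among the 88.

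TCRγδ+ ILTC1 cells were compared with TCRγδ+NK1.1− cells to ask the same of γδ T cells. Gzmc was at 968 ± 368 and 15.8 ± 0.633 CPM (5.94 ± 0.59, adjusted p = 0.00511), and Gzmb at 10489.8 ± 1909 and 2249.6 ± 556 CPM (2.22 ± 0.41, adjusted p = 0.0333). Tnfsf10 (2.35 ± 0.29, adjusted p = 0.00968), Itga1 (2.29 ± 0.36, adjusted p = 0.0211), Klrb1c (7.20 ± 1.07, adjusted p = 0.0175) and Ncr1 (7.47 ± 1.30, adjusted p = 0.0334) were higher in ILTC1 cells. Tbx21 was also higher (1.83 ± 0.37, adjusted p = 0.0448). Sox13, which encodes a factor of interleukin 17-producing γδ T cells, had 0 counts against 43.4 ± 8.16 CPM, at least 377-fold lower (adjusted p = 0.0452). Cd163l1, a scavenger receptor gene of such cells, had 2 counts in the ILTC1 libraries and 679 ± 141 CPM in TCRγδ+NK1.1− cells (adjusted p = 0.012).

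In total 268 genes differed, 113 higher and 155 lower. With the size factors of RLE, a scaling by median ratios, they were 79 higher and 173 lower of 252, and the median of all genes lay at −0.268 with that scaling and −0.134 with TMM, a shift of −0.134. Xcl1 (2.57 ± 0.37, adjusted p = 0.0157), the interleukin receptor genes Il2rb (2.00 ± 0.33, adjusted p = 0.0251) and Il2rg (1.51 ± 0.24, adjusted p = 0.0211) and the signalling gene Stat4 (1.86 ± 0.24, adjusted p = 0.012) were higher. TCRγδ+NK1.1− libraries held 19535 and 48216 CPM of myeloid genes, which can lower the share left for lymphocyte RNA. Cd3e was at 1374 against 708 CPM and Cd3g at 2387 against 1221 CPM, though the T-cell receptor signalling list had a median of 0.08. How far a lower share adds to the rises here, among them Il2rg, Stat4, Tbx21 and the cell cycle list, was not tested. Gzmk (−3.72 ± 0.54, adjusted p = 0.0159) and Icos, a costimulator gene (−2.47 ± 0.45, adjusted p = 0.0329), were lower. Fcer1g (1.88 ± 0.41, adjusted p = 0.0586), Itgae (1.41 ± 0.61, adjusted p = 0.265) and Pdcd1 (−2.36 ± 0.51, adjusted p = 0.0538) were not called. Genes of other cells were lower in ILTC1 cells, with the macrophage lysozyme gene Lyz2 at 10.3 ± 5.01 and 3317 ± 1705 CPM and the casein gene Csn3 at 0.639 ± 0.904 and 1118 ± 666 CPM.

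NK receptor genes were higher, 16 of 30 called and 14 not (27 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.5e-48), with a median of 4.12. Type 3 genes, a list set to mark interleukin 17-producing cells, were lower with a median of −7.79, 4 of 17 called (all 17 adjusted over the list alone, camera adjusted p = 4.48e-25). Not all members mark such cells here. Kcnk1 was at 37.1 and 28.1 and Il17re at 17.6 and 9.87 CPM in the TCR−NK1.1+ libraries, which held epithelial genes. Sox13 was at 1.24 and 1.81 CPM there. How much of the list follows RNA of other cells was not tested. The cytotoxicity list was higher, 7 of 20 called and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 6.57e-09). So were the residency list, 5 of 20 called (9 and 1 lower adjusted over the list alone; camera adjusted p = 1.48e-07), and the type 1 list, 3 of 15 called (6 and 1 lower adjusted over the list alone; camera adjusted p = 0.000479, adjusted p = 0.0901 with an estimated correlation). Lower as well were the myeloid list, 6 of 20 called (camera adjusted p = 2.53e-16, adjusted p = 0.0901 with an estimated correlation), and the epithelial list, 5 of 15 (camera adjusted p = 8.63e-18). Lower among smaller lists were the stromal list, 1 of 9 (camera adjusted p = 0.000156, adjusted p = 0.066 with an estimated correlation), and the erythroid list, 1 of 4 (camera adjusted p = 1.22e-05, adjusted p = 0.0877 with an estimated correlation). Of 17 glycolysis genes 1 was lower (camera adjusted p = 0.0237, adjusted p = 0.333 with an estimated correlation). The cell cycle list, with none of 28 genes called, lay on the higher side (camera adjusted p = 0.00691, adjusted p = 0.0901 with an estimated correlation).

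Without TCRγδ+ ILTC1 replicate 1 or 2 the calls numbered 35 and 7, and without TCRγδ+NK1.1− replicate 1 or 2 they numbered 804 and 303. Gzmc kept its call in all 4 fits, Klrb1c in 3, Tnfsf10, Itga1, Ncr1, Cd163l1, Xcl1, Il2rb, Il2rg, Stat4, Gzmk, Icos, Lyz2 and Csn3 in 2, Gzmb in 1, and Tbx21 and Sox13 in none. Without genes that followed the epithelial list, chosen after seeing the data, 140 genes were called, 65 higher and 75 lower, all 140 among the 268.

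**Figure D2:**
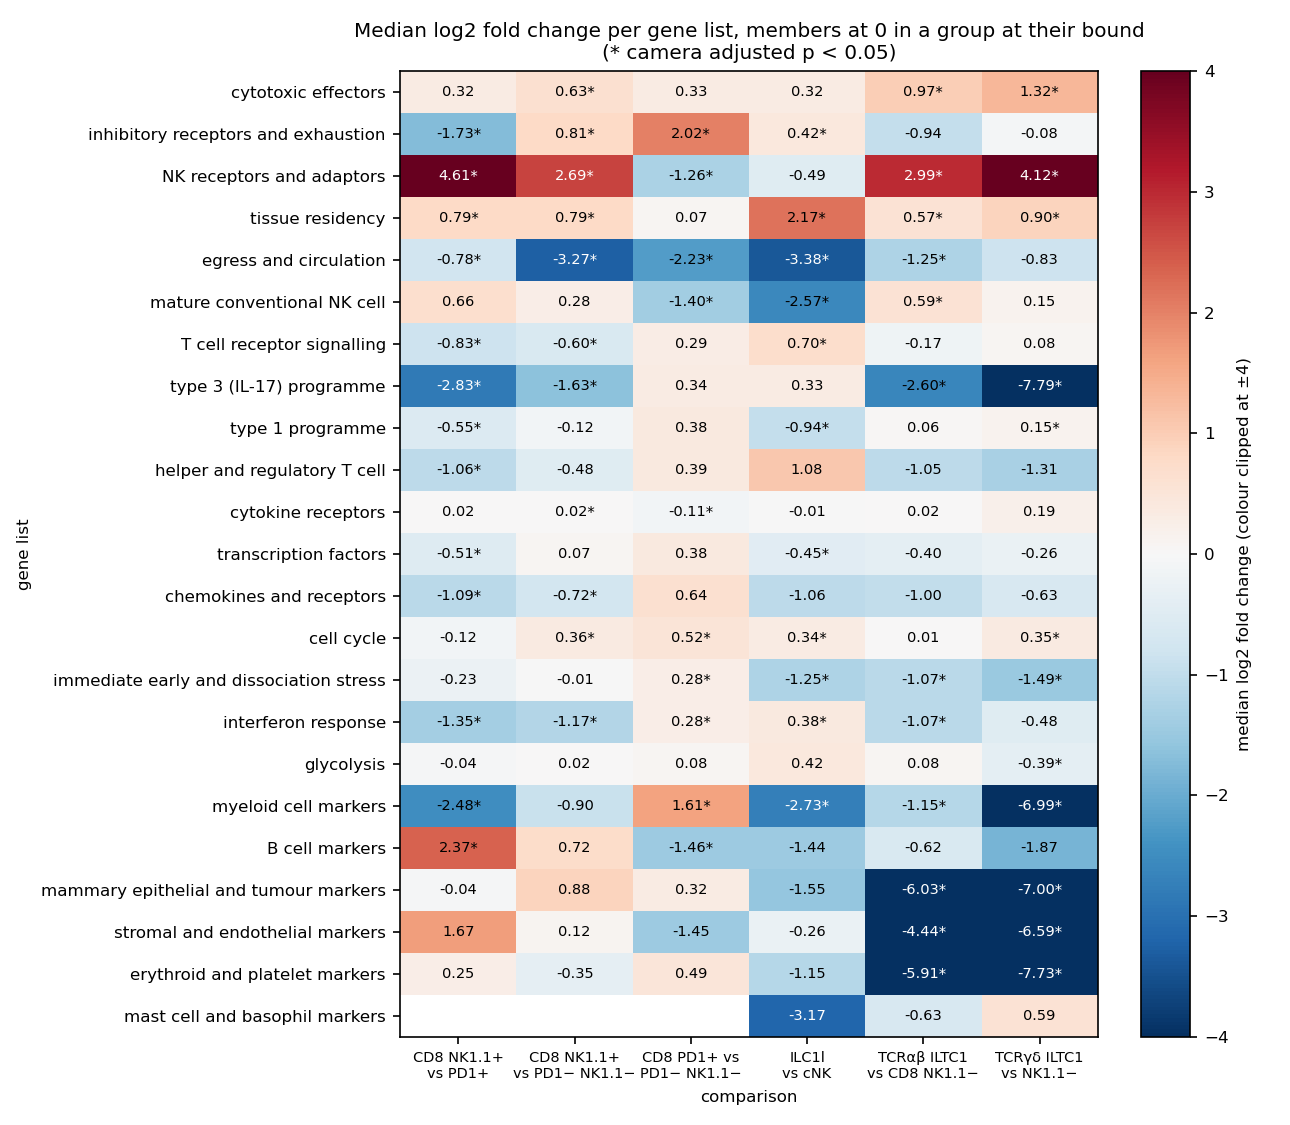
Median log2 fold change of each of 23 gene lists (vertical) in 6 comparisons of populations (horizontal), with members at 0 counts in a group set to their bound, colour clipped at ±4 and * for a camera adjusted p under 0.05. The NK receptor list had a median of 4.61, 2.69, 2.99 and 4.12 where NK1.1+ or ILTC1 T cells were compared with T cells lacking NK1.1, and −0.49 for ILC1l against cNK cells.

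The innate-like populations of the second set were next compared with each other. Between TCRαβ+ ILTC1 and ILC1l cells, edgeR called no gene, with 1072 of 16828 genes at an unadjusted p under 0.05 and 257 called by DESeq2. That share is slightly above the 0.05 that no difference at all would give. Gzmc was at 363 ± 151 and 3491 ± 61.2 CPM (−3.27 ± 0.52, adjusted p = 0.209). Prf1 was at 148 ± 9.09 and 555 ± 51.9 CPM (−1.91 ± 0.41, adjusted p = 0.46), and Cd3e at 1550.2 ± 230 and 283 ± 275 CPM (2.46 ± 0.86, adjusted p = 0.728). Itga1 (0.31 ± 0.34, adjusted p = 0.853) and Gzmb (0.38 ± 0.39, adjusted p = 0.835) differed by less than their SE. As a list, T-cell receptor signalling genes were higher in TCRαβ+ ILTC1 cells (14 of 20 adjusted over the list alone; camera adjusted p = 2.2e-24). The myeloid list lay higher in them too (median 2.17; camera adjusted p = 0.00447, adjusted p = 0.588 with an estimated correlation), and lower without TCRαβ+ ILTC1 replicate 1 (camera adjusted p = 0.0324). Without TCRαβ+ ILTC1 replicate 1 the calls numbered 324, and without any other of the 4 libraries 1 or fewer.

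Between TCRγδ+ and TCRαβ+ ILTC1 cells edgeR also called no gene, with 570 of 16828 at an unadjusted p under 0.05 and 77 called by DESeq2. That share is below the 0.05 that no difference at all would give. Cd8b1, the CD8β chain gene, was at 3.16 ± 4.03 and 238 ± 68 CPM (−6.22 ± 1.44, adjusted p = 1). Cd8a was at 269.5 ± 101 and 1974 ± 433 CPM (−2.87 ± 0.84, adjusted p = 1), and Gzmc at 968 ± 368 and 363 ± 151 CPM (1.41 ± 0.48, adjusted p = 1). T-cell receptor signalling genes were lower as a list in TCRγδ+ cells (1 of 20 adjusted over the list alone; camera adjusted p = 0.00667, adjusted p = 0.737 with an estimated correlation). Without TCRαβ+ ILTC1 replicate 1 the calls numbered 297, and without any other of the 4 libraries 0.

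**Figure D3:**
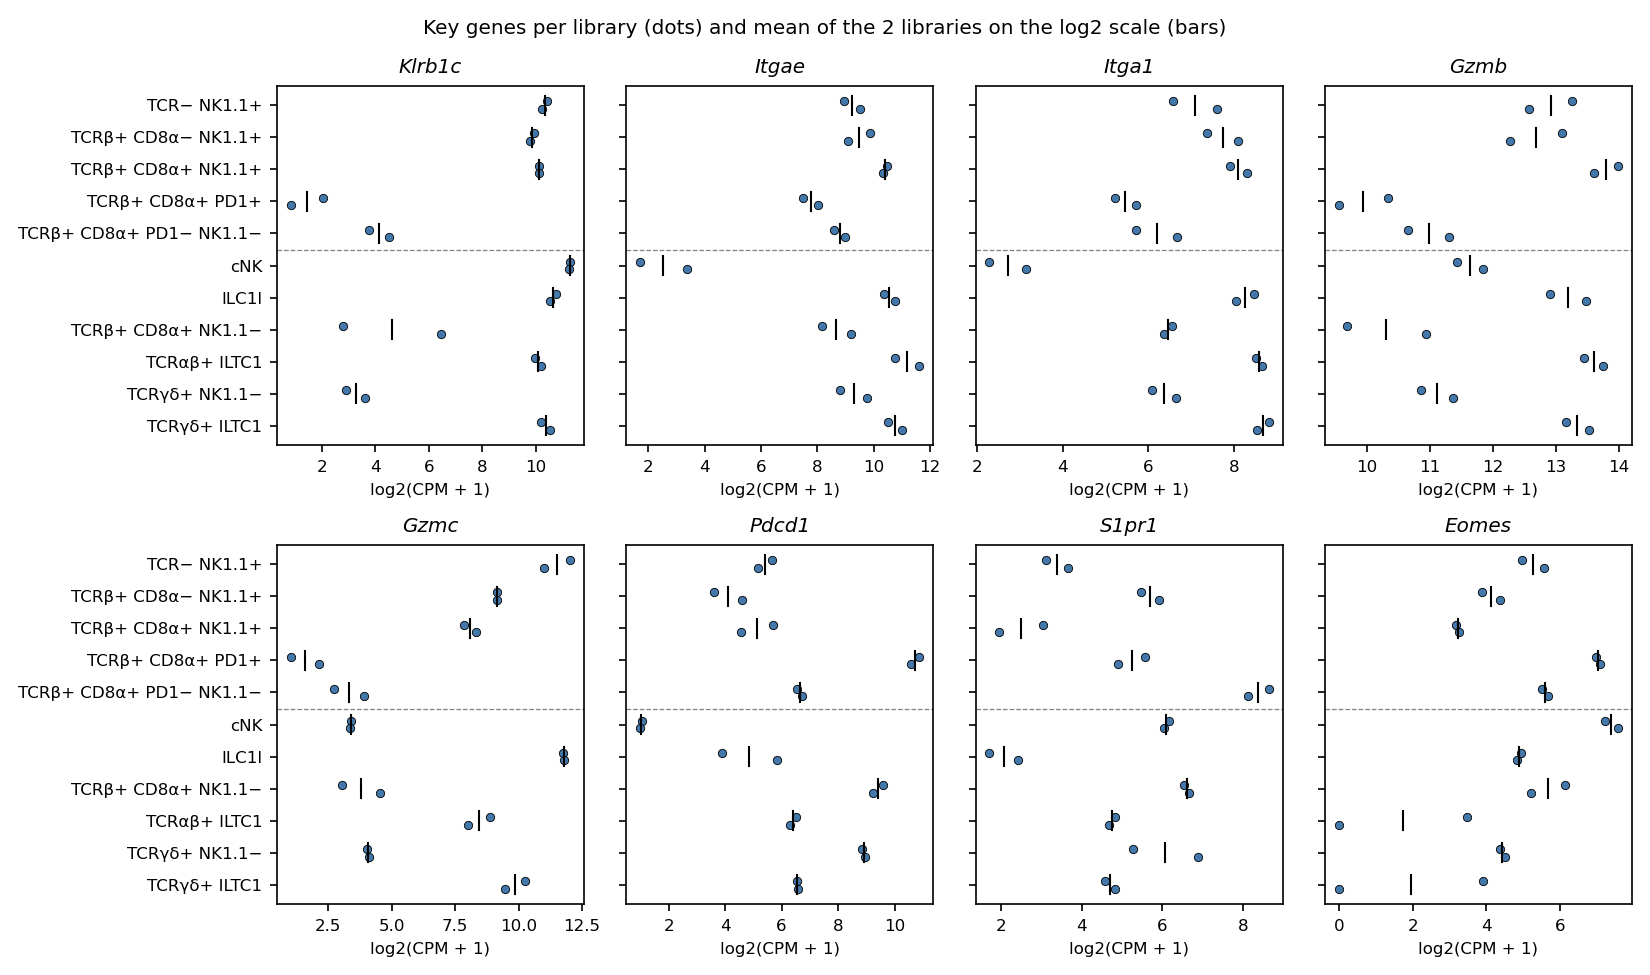
CPM of 8 genes on a log2(CPM + 1) axis, 1 dot per library and bars at the mean of 2 libraries on that scale, for 11 populations. Gzmc averaged 3491 CPM in ILC1l, 968 in TCRγδ+ ILTC1 and 363 in TCRαβ+ ILTC1 cells, against 9.37 in cNK cells, 15.8 in TCRγδ+NK1.1− and 14.6 in TCRβ+CD8α+NK1.1− cells.

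The mean of the 3 differences (ILC1l against cNK, and each ILTC1 population against its NK1.1− counterpart) asked what changes on average across lineages; a change in the mean need not be in all 3. Gzmc (6.37 ± 0.35, adjusted p = 0.000107), Itga1 (3.38 ± 0.22, adjusted p = 0.000123), Tnfrsf9 (1.85 ± 0.12, adjusted p = 0.000144) and Tnfsf10 (2.27 ± 0.17, adjusted p = 0.000275) were higher in the innate-like populations. Itgae (3.98 ± 0.39, adjusted p = 0.000789), Xcl1 (2.58 ± 0.21, adjusted p = 0.000546) and Gzmb (2.32 ± 0.24, adjusted p = 0.00105) were higher too. S1pr1 (−2.62 ± 0.31, adjusted p = 0.00202), Gzmk (−3.14 ± 0.31, adjusted p = 0.000789), Il7r (−1.93 ± 0.35, adjusted p = 0.0128), Ifng (−1.14 ± 0.21, adjusted p = 0.0122) and Nr4a2, an immediate early gene (−1.56 ± 0.18, adjusted p = 0.00163), were lower. These genes kept their calls without each of the 12 libraries in turn. Some rest on part of the comparisons: in the order ILC1l, αβ and γδ, Il7r was at −0.01, −3.18 and −2.61, Gzmk at −1.02, −4.69 and −3.72, Ifng at −2.36, −0.79 and −0.27, Nr4a2 at −2.65, −1.95 and −0.09, and Itgae at 8.05, 2.49 and 1.41.

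In this mean 987 genes differed, 319 higher and 668 lower. Zfp683 (3.46 ± 0.68, adjusted p = 0.0182) and Ccr8, a chemokine receptor gene (2.04 ± 0.40, adjusted p = 0.0175), were higher, and kept their calls in 8 and 10 of the 12 fits without 1 library. Tbx21 (0.44 ± 0.21, adjusted p = 0.276), Prf1 (−0.59 ± 0.23, adjusted p = 0.182) and Eomes (−2.49 ± 0.99, adjusted p = 0.194) were not called. Of 20 residency genes 14 were higher, 1 lower and 5 not called (15 and 3 adjusted over the list alone; camera adjusted p = 3.07e-26). Of 30 NK receptor genes 20 were higher and 10 not called (27 higher adjusted over the list alone; camera adjusted p = 2.95e-53). Of 20 cytotoxicity genes 6 were higher and 2 lower (9 and 4 adjusted over the list alone; camera adjusted p = 7.1e-08). Immediate early genes were lower, 11 of 19 called (15 adjusted over the list alone; camera adjusted p = 7.65e-18). So were egress genes, 10 of 18 (13 adjusted over the list alone; camera adjusted p = 1.06e-11), and type 3 genes, 6 of 17 (9 adjusted over the list alone; camera adjusted p = 1.93e-07).

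Several of these lists differed between the 3 comparisons. The NK receptor list, not called for ILC1l against cNK cells, lay higher in the αβ (camera adjusted p = 2e-38) and the γδ comparison (2.56e-30) than in that of ILC1l, by interaction contrasts. ILC1l and cNK cells both held Klrb1c (1605 ± 174 and 2460.2 ± 31.8 CPM), whereas the other comparisons are with cells sorted as NK1.1−. For this list a difference between lineages therefore cannot be told apart from the sorts. The type 3 list had 1 of 17 genes higher and none lower in ILC1l (camera adjusted p = 0.506). For TCRαβ+ ILTC1 cells it was lower (3.93e-05, adjusted p = 0.0889 with an estimated correlation). It lay lower in the γδ than in the ILC1l comparison (6.24e-08), and in the αβ than in the ILC1l comparison (0.00112, adjusted p = 0.12 with an estimated correlation). The type 3 list members Kcnk1 and Il17re were at 22.8 and 40.5 and at 8.68 and 21.3 CPM in the TCRβ+CD8α+NK1.1− libraries, which held epithelial genes. The residency list rose less in the αβ (4.54e-15) and γδ (1.29e-07) than in the ILC1l comparison. Its members Itgae and Itga1 were at 5.75 and 5.85 CPM in cNK, 435 and 87.2 CPM in TCRβ+CD8α+NK1.1− and 658 and 83.1 CPM in TCRγδ+NK1.1− cells. In ILC1l, TCRαβ+ and TCRγδ+ ILTC1 cells Itgae was at 1519, 2442 and 1753 CPM and Itga1 at 308, 381 and 408 CPM. For these genes a smaller rise cannot be told apart from the higher level in the comparison cells. The egress list lay higher in the αβ (4.57e-09) and γδ comparisons (5.71e-07, adjusted p = 0.107 with an estimated correlation) than in that of ILC1l. Its medians were −3.38 for ILC1l, −1.25 for the αβ and −0.83 for the γδ comparison. For the immediate early list neither difference was called (0.185 and 0.427).

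Genes of other cell types made up part of the 668 lower genes: 11 of 15 epithelial genes (camera adjusted p = 2.81e-16) and 15 of 20 myeloid genes (camera adjusted p = 2.14e-15, adjusted p = 0.0952 with an estimated correlation) were lower. Without genes that followed the epithelial list, chosen after seeing the data, 545 were called, 227 higher and 318 lower, 543 of them among the 987. With the TCRγδ+ populations left out of the mean, also chosen after seeing the data, 437 were called, 201 higher and 236 lower, 367 of them among the 987. Leaving out 1 library moved the count past 1.5 times for ILC1l replicates 1 and 2 (553 and 448), cNK replicates 1 and 2 (649 and 543), TCRγδ+ ILTC1 replicate 2 (466), TCRβ+CD8α+NK1.1− replicate 2 (607), TCRαβ+ ILTC1 replicate 1 (1783) and TCRγδ+NK1.1− replicate 1 (1836).

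The 3 comparisons share no library, though they share 1 fit and its gene-wise spread, and genes called in all of them were counted. Higher in all 3 were 7 genes, against 0.0017 if the calls were independent. They were Gzmc (8.54, 4.64 and 5.94 for ILC1l, TCRαβ+ and TCRγδ+ ILTC1 cells), Itga1 (5.72, 2.13 and 2.29), Tnfrsf9 (1.46, 2.03 and 2.06), Xcl1 (2.46, 2.72 and 2.57), the T-cell surface gene Cd7 (3.33, 2.61 and 2.03), the Ly49 receptor gene Klra5 (3.63, 3.25 and 4.69) and the carbonic anhydrase gene Car2 (1.75, 1.99 and 2.52). Lower in all 3 were 4 genes, against 0.0018: the immediate early genes Nr4a1 (−2.93, −1.61 and −1.68) and Zfp36 (−1.96, −1.92 and −2.61), the kinase gene Sgk1 (−3.52, −3.27 and −3.30) and the epithelial junction gene Cldn4. Nr4a1 and Zfp36 both stand in the list of immediate early and dissociation stress genes. With only the libraries compared in each fit, edgeR called 0 genes between TCRαβ+ ILTC1 and TCRβ+CD8α+NK1.1− cells and so no shared gene, beside 2327 genes at an unadjusted p under 0.05 for that pair in the fit with all 12 libraries and 95 shared genes by DESeq2. Without each of the 12 libraries in turn the shared genes numbered 2 to 11. The count was 2 without TCRγδ+ ILTC1 replicate 2 or TCRβ+CD8α+NK1.1− replicate 2, 3 without replicate 1 of cNK or of TCRβ+CD8α+NK1.1− cells or replicate 2 of TCRαβ+ ILTC1 cells, 4 without replicate 2 of ILC1l or of cNK cells, 5 without TCRγδ+ ILTC1 replicate 1, and 7 without ILC1l replicate 1.

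The NK1.1+ CD8α+ T cells of the first set and the TCRαβ+ ILTC1 cells of the second were each compared with αβ CD8α+ T cells lacking NK1.1, and their log2 fold changes were set side by side over the 15194 genes tested in both. Across genes, which are not independent replicates, Pearson's r was 0.219 and Spearman's rho 0.286. The sign was the same in 59.8% of all genes, in 265 of 279 genes called in the first set and in 71 of 88 called in the second. Both comparisons called 29 genes higher, against 0.39 if independent, and 7 lower, against 0.42. Among them, named after their values were seen, were Gzmb (2.80 and 3.17), Gzmc (4.80 and 4.64), Fcer1g (3.92 and 3.64), the signalling adaptor gene Tyrobp (4.74 and 3.67), Klra7 (3.65 and 4.78) and Cd7 (2.76 and 2.61). Lower in both were Cd28 (−4.66 and −3.94), Gzmk (−2.95 and −4.69) and Anxa1, which encodes a phospholipid-binding protein (−3.57 and −2.92). The transferrin gene Trf was called in opposite directions (3.30 and −4.62). Without 1 library Pearson's r ranged from 0.099, without PD1−NK1.1− replicate 1, to 0.268, without NK1.1+ replicate 2, and was 0.12 without PD1−NK1.1− replicate 2.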

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

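Tests of the keratin and casein transcripts and of T cells among ILC1l cells were chosen after the results were seen; all 3 patterns were picked after looking at the data. For the correlation of the 2 sets, a requirement that the value stay on its side of the bound without each library in turn was added after the first values had been seen; it left both affected tests undecided.

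The differences between ILTC1 cells and their NK1.1− counterparts, and between ILC1l and cNK cells, were set against each other in interaction contrasts of edgeR's quasi-likelihood test, and genes whose difference itself passed are listed. TCRαβ+ ILTC1 minus ILC1l gave 43 such genes, 13 higher and 30 lower, with a median of all genes at −0.193. As3mt, a methyltransferase gene (8.29, adjusted p = 0.00672), and the Ly49 genes Klra1 (5.45, adjusted p = 0.0316) and Klra7 (5.26, adjusted p = 0.00597) lay higher in the αβ comparison than in that of ILC1l with cNK cells. Itga1 (−3.59, adjusted p = 0.0271), Itgae (−5.56, adjusted p = 0.0497), Pdcd1 (−8.10, adjusted p = 0.00597) and Adora3 (−8.51, adjusted p = 0.0357) lay lower in it. Pdcd1 was at 83.7 CPM in TCRαβ+ ILTC1 and 34.6 CPM in ILC1l cells, beside 694 CPM in TCRβ+CD8α+NK1.1− and 1.03 CPM in cNK cells. In the same order Itgae was at 2442, 1519, 435 and 5.75, Klra7 at 823, 616, 29.9 and 854 and As3mt at 7.58, 0.569, 5.49 and 131 CPM. These contrasts hold the levels of the comparison cells and need not show a difference between ILTC1 and ILC1l cells. Without each of the 8 libraries in turn the count ran from 4 (without cNK replicate 1) to 418 (without TCRαβ+ ILTC1 replicate 1). It was 22 and 17 without ILC1l replicates 1 and 2, 10 without cNK replicate 2, 13 without TCRαβ+ ILTC1 replicate 2 and 20 without TCRβ+CD8α+NK1.1− replicate 2. Klra7 kept its call in all 8 fits, Pdcd1 in 7, As3mt in 6, Itgae in 3, Itga1 and Klra1 in 2 and Adora3 in 1.

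TCRγδ+ ILTC1 minus ILC1l gave 171 genes, 97 higher and 74 lower, with a median of all genes at −0.332, or −0.462 with RLE scaling. Higher were Klra13-ps (10.26, adjusted p = 0.0119), Klrb1c (7.81, adjusted p = 0.0303), the receptor gene Klrc2 (6.82, adjusted p = 0.0437), Prf1 (3.13, adjusted p = 0.0382) and Tbx21 (2.77, adjusted p = 0.0407). The Klrb1c difference is built into the sorts. ILC1l and cNK cells both held Klrb1c (1605 and 2460.2 CPM), whereas the γδ comparison is with NK1.1− cells. Prf1 was at −2.57 for ILC1l against cNK cells and 0.55 in the γδ comparison, and Tbx21 at −0.94 and 1.83. Lower were Itga1 (−3.43, adjusted p = 0.0178), Itgae (−6.64, adjusted p = 0.0158), Cd8a (−7.32, adjusted p = 0.0348) and Pdcd1 (−7.41, adjusted p = 0.00429). Itgae was at 1753 CPM in TCRγδ+ ILTC1 and 1519 CPM in ILC1l cells, beside 658 CPM in TCRγδ+NK1.1− and 5.75 CPM in cNK cells. In the same order Pdcd1 was at 93.4, 34.6, 478 and 1.03 CPM, so these contrasts too hold the levels of the comparison cells. For ILC1l against cNK cells Cd8a was at 6.85 and Pdcd1 at 5.05. In the ILC1l libraries Cd8a was at 52.9 and 256, Pdcd1 at 13.9 and 55.4 and Cd3e at 88.4 and 477 CPM, so T cells among ILC1l cells may add to these values. Without each of the 8 libraries in turn the count was 47 and 50 (ILC1l replicates 1 and 2), 38 and 50 (cNK), 38 and 27 (TCRγδ+ ILTC1), and 506 and 450 (TCRγδ+NK1.1−). Pdcd1 kept its call in all 8 fits, Itgae and Klra13-ps in 6, Itga1 and Cd8a in 4, and Klrb1c, Klrc2, Prf1 and Tbx21 in 2.

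TCRγδ+ minus TCRαβ+ ILTC1 gave 9 genes, 7 higher and 2 lower, with a median of all genes at −0.114. They included Atp8b4, a lipid transporter gene (4.12, adjusted p = 0.0156), the nuclear RNA Malat1 (3.43, adjusted p = 0.041) and the kinase gene Clk1 (3.10, adjusted p = 0.041). Atp8b4 was at 310.3 CPM in TCRγδ+ and 153 CPM in TCRαβ+ ILTC1 cells, beside 38.7 CPM in TCRγδ+NK1.1− and 333 CPM in TCRβ+CD8α+NK1.1− cells. In the same order Malat1 was at 3649.7, 1170.5, 1625 and 5606 CPM, so the NK1.1− cells contribute to both contrasts. Malat1 also varied between replicates, at 12685 and 3776 CPM in the PD1+ libraries. The count was 0 without either TCRγδ+ ILTC1 library or either TCRβ+CD8α+NK1.1− library, 291 and 2 without TCRαβ+ ILTC1 replicates 1 and 2, and 229 and 24 without TCRγδ+NK1.1− replicates 1 and 2. Atp8b4 and Clk1 kept their calls in 4 of 8 fits and Malat1 in 3.

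The first pattern is the keratin and casein transcripts in sorted lymphocytes. TCRβ+CD8α+NK1.1− cells of the second set held 1740 and 3204 CPM of epithelial genes, while the PD1+ and PD1−NK1.1− populations of the first set, the same lineage by surface marker, held 46.55 CPM or less. Transcription by these lymphocytes would need similar sums in both, but the lowest of the former was 37.4 times the highest of the latter, which argues against it. These are the sums in which the pattern was seen, so this is no separate test. RNA of other tumour cells in the libraries is a candidate source: erythroid and platelet genes, which such RNA would bring along, were also higher, the smallest of 3 ratios, for TCR−NK1.1+, TCRβ+CD8α+NK1.1− and TCRγδ+NK1.1− cells, being 10; TCRβ+CD8α−NK1.1+ libraries, outside this test, held 13.03 and 1.04 CPM. The sort for a T-cell receptor, or for NK1.1 in TCR−NK1.1+ cells, would remove intact epithelial cells, and whether free RNA or attached cells may carry these transcripts was not tested.

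The second pattern is Cd3 transcripts in ILC1l, with Cd3e at 88.4 and 477 CPM. If T cells among the sorted cells were the source, shares of 2.1% αβ and 1.79% γδ T cells in replicate 1 and 16.2% and 7.22% in replicate 2, taken from receptor transcripts, would imply fewer Cd3 transcripts than measured: the median ratio over 3 genes was 2.01 in replicate 1, just past the upper bound of 2 set for that source, and 1.53 in replicate 2, within it. Receptor constant-region transcription without a rearranged receptor would lower the number of V counts per C count, which was 0.126 of that in TCRαβ+ ILTC1 cells in the lower library (0.0482 and 0.198 per C count in ILC1l, 0.382 and 0.384 in TCRαβ+ ILTC1, over 53 V segments). The ILC1l libraries fall on different sides of the bound in both measures. The V counts per C count cannot separate the explanations, because cNK libraries also held C counts with few V counts. These were 4120 and 4097 C counts at 0.00413 and 0.00903 V counts each, beside 5541 and 9728 C counts in ILC1l. T cells on such a background would lower the ratio too. In the cNK libraries Cd3e was at 0.622 and 6.13 CPM. V counts numbered 267 and 1923 in the ILC1l libraries, against 17 and 37 in the cNK libraries. Trac (24.3 and 138 CPM), Tcrg-V4 (5.91 and 27.3 CPM) and Cd8a (52.9 and 256 CPM) rose with Cd3e from ILC1l replicate 1 to 2. These values argue against constant-region transcription as the only source. Cd3g was at 3.45 and 2.09 times the level that T cells would imply, so how much each explanation adds cannot be told.

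The third pattern is the low correlation of 0.219 across genes between the 2 sets' NK1.1+ or ILTC1 αβ comparisons. Without genes that follow the epithelial or myeloid lists r was 0.287 (0.155 to 0.332 without 1 library in turn, 14357 genes). That lies under the 0.3 set against RNA of other cells, which the range crosses, and no value reached the 0.4 set for it. Over the 6860 genes with at least 20 CPM r was 0.413 (0.335 to 0.492), above the 0.4 set for counting noise, which that range crosses. Set against the mean of PD1+ and PD1−NK1.1− cells, since NK1.1− cells of the second set may hold both, it was 0.287 (0.196 to 0.328). That rise from 0.219 lies between the bounds set for and against it. Leaving out genes that follow the lists raised r to the same 0.287, and it drops only genes with a correlation above 0.8. RNA of other cells in further genes would remain. The cut at 20 CPM may also drop genes of other cells that are low in most libraries, so it does not single out counting noise. Neither value stays on its side of the bound without each library. RNA of other cells, counting noise and PD1+ cells therefore stay open.

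For the mean of 3 differences, which called 987 genes, splits of the 12 libraries into 6 and 6 were compared in a fit of 2 groups. Of 100 drawn from 462 splits, 1 gave as many calls as the real split, the real one itself, with 434 calls against at most 0 in the others by edgeR. Splits of single libraries part replicates of unlike populations, which widens the spread within each group, so these counts decide nothing, a judgement made after they were seen. Splitting by whole populations, the real split of 10 gave 987 calls, and the others 32 to 368; 10 splits are too few for a share under 0.05.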

How the results depend on the processing

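Fits without genes that follow the epithelial or myeloid lists and the mean without TCRγδ+ populations were chosen after the results were seen; the other alternatives were planned. Unless stated, the cause of a moved count was not tested.

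In the first set, NK1.1+ CD8α+ cells were compared with PD1+ (332 calls), PD1−NK1.1− (280), TCR−NK1.1+ (242) and TCRβ+CD8α−NK1.1+ cells (53), and PD1+ with PD1−NK1.1− cells (71). Without a filter on low counts these became 838, 747, 1452, 906 and 397, and with DESeq2 886, 800, 1143, 614 and 404. With all 22 libraries in 1 fit they became 221, 168, 72, 17 and 45, and at an adjusted p under 0.01 they were 147, 69, 28, 12 and 9. With only the libraries compared, the first 4 became 717, 531, 1595 and 3. A filter of 1 CPM gave 94 calls against TCRβ+CD8α−NK1.1+ cells. Without genes that follow the epithelial list the counts were 116 against TCR−NK1.1+, 22 against TCRβ+CD8α−NK1.1+ and 114 for PD1+ against PD1−NK1.1− cells, and without those that follow either list 106, 21 and 119.

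In the second set, ILC1l were compared with cNK cells (171 calls), TCRαβ+ ILTC1 with TCRβ+CD8α+NK1.1− cells (88) and TCRγδ+ ILTC1 with TCRγδ+NK1.1− cells (268), and the mean of these differences was tested (987). Without a filter these became 787, 1244, 1786 and 2233, with DESeq2 916, 1357, 1886 and 2439, and with all 22 libraries in 1 fit 327, 282, 626 and 1517. At an adjusted p under 0.01 they were 65, 1, 21 and 296. With only the libraries compared, the first 3 became 1519, 0 and 172; the 0 is edgeR's, beside 2327 genes at an unadjusted p under 0.05 in the fit with all 12 libraries. Without genes that follow the epithelial list the last 3 were 39, 140 and 545, and without those that follow either list the last 2 were 158 and 531. The mean without TCRγδ+ populations called 437.

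For the comparisons with no call, TCRαβ+ ILTC1 against ILC1l and TCRγδ+ against TCRαβ+ ILTC1 cells, there were 344 and 154 calls without a filter and 257 and 77 with DESeq2, and 9 for the first with all 22 libraries in 1 fit. The differences between the 3 comparisons (αβ minus innate 43, γδ minus innate 171, γδ minus αβ 9) became 738, 1320 and 479 without a filter, 584, 1415 and 459 with DESeq2, and 143, 458 and 31 with all 22 libraries in 1 fit. At an adjusted p under 0.01 they were 9, 27 and 0, and γδ minus αβ was 0 with only the libraries compared, by edgeR in both cases, beside 1489 genes at an unadjusted p under 0.05. The 11 genes shared by the 3 comparisons became 161 without a filter, 95 with DESeq2, 21 with all 22 libraries in 1 fit, and 0 at an adjusted p under 0.01 or with only the libraries compared. Pearson's r of 0.219 between the sets became 0.142 without a filter, 0.132 with DESeq2 and 0.377 with only the libraries compared.

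Leaving out 1 library in turn, with the lone library assumed to vary like the other populations, gave ranges of 116 to 170, 46 to 105, 3 to 137, 2 to 667 and 14 to 30 calls in the first set, in the order above. In the second set the ranges were 34 to 79, 11 to 840, 7 to 804 and 448 to 1836, then 0 to 324 and 0 to 297 between innate-like populations, and 4 to 418, 27 to 506 and 0 to 291 for the differences between comparisons. Shared genes numbered 2 to 11, Pearson's r ran from 0.099 to 0.268, and 143 to 154 of the list tests passed.

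Of 322 list tests 148 passed, against 41 with an estimated correlation. Camera's side changed in 7 cases, given with the range of adjusted p without 1 library in turn. The immediate early list did so for NK1.1+ against PD1−NK1.1− cells without PD1−NK1.1− replicate 2 (0.0262; range 0.0102 to 0.587) and for PD1+ against PD1−NK1.1− cells without PD1−NK1.1− replicate 1 (0.792; 2.66e-07 to 0.792). The NK receptor list did so for ILC1l against cNK cells with only the libraries compared (0.0169; 0.356 to 0.95). Without TCRαβ+ ILTC1 replicate 1 the interferon list (0.0167; 0.0162 to 0.855) and the myeloid list (0.0324; 6.45e-32 to 0.0324) changed side against ILC1l. The myeloid list also did against TCRγδ+ ILTC1 cells (0.00107; 6.88e-28 to 0.35) and in αβ minus innate (0.00196; 2.57e-10 to 0.63). Over all alternatives, named genes kept direction and side of the threshold in 7759 values, lost the call in 1312 and gained it in 149, and none changed direction; list tests did so in 3919, 230 and 128.

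The replicate numbers are shared by populations, but the labels do not say that they pair libraries, and not every pair deviated together: the correlation of same-numbered libraries was 0.055 to 0.227 in the first set (8 of 10 pairs over 0.1, the 3 among CD8α+ populations at 0.203, 0.216 and 0.227) and −0.041 to 0.123 in the second (1 of 15). With the replicate number as a block, calls became 421 against PD1−NK1.1− cells, 387 against TCR−NK1.1+ cells, 125 for PD1+ against PD1−NK1.1− cells, and 17 for the shared genes. Other counts stayed within 1.5 times. Among named genes 26 values lost the call with this block and 10 gained it, and among list tests 10 lost and 3 gained it.

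Alternatives planned for normalised values were not run, because the table holds counts. Depth limits genes under 0.146 to 0.345 CPM, the value of 3 counts in a library.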

Other observations

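The values in this part were chosen after they were seen, and no test was run on the segments or the ratios. Receptor segments differed between the γδ populations. Tcrg-V6 was at 181 and 92.7 CPM in the TCRγδ+NK1.1− libraries and at 4.13 and 3.13 CPM in the TCRγδ+ ILTC1 libraries. Tcrg-V4 was at 91.9 and 79.5 CPM against 257 and 292 CPM. Among δ segments, Trdv4 was at 395 and 284 CPM in TCRγδ+NK1.1− and 24.3 and 43.4 CPM in TCRγδ+ ILTC1 libraries, and Trdv5 at 24.7 and 19.5 against 54.3 and 84 CPM. Trdv4 was also at 52.1 and 53 CPM in cNK and 35.5 and 37.7 CPM in ILC1l libraries, so its level in TCRγδ+ ILTC1 libraries need not reflect receptor use. Segment names are those of the table, and V segments are near-identical in part, so counts may be shared between them.

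The ratio of Cd8b1 to Cd8a CPM, which compares the CD8β chain gene with that of the CD8α chain, was 0.161 and 0.183 in NK1.1+ CD8α+ libraries and 0.171 and 0.0831 in TCRαβ+ ILTC1 libraries. It was 1.27 and 1.56 in PD1+, 1.54 and 1.41 in PD1−NK1.1−, and 0.956 and 0.559 in TCRβ+CD8α+NK1.1− libraries. Cd8b1 itself was called in none of the pairwise comparisons of these populations in the main fit of edgeR's quasi-likelihood test. With only the libraries compared in the fit it was called lower in NK1.1+ CD8α+ than in PD1+ and PD1−NK1.1− cells, at an adjusted p under 0.05. Without a filter on low counts it was also called lower in TCRαβ+ ILTC1 than in TCRβ+CD8α+NK1.1− cells.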
